A study of Mus musculus with 6 samples.

How the data were processed

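The series holds 6 samples of mouse aorta, 3 from mice on a normal diet and 3 on a high-fat diet. Per the labels' protocols, aortas were digested with 0.2% type IA collagenase and DNase for 30 min at 37 °C, strained at 40 μm, treated with a red cell lysis buffer and loaded on a droplet controller with version 2 gel beads for 3′ transcript tags. Per the submitters' processing notes, Cell Ranger 3.0 and the mm10 build were used. The deposited matrices hold UMI counts per gene and cell for 27998 genes, identical in order in all 6 samples. How cells were called, which annotation was used and whether wells were brought to equal depth is not stated. Barcode suffixes show that each deposited count matrix joins cells from 2 gel-bead wells. The matrices of control 1 and control 3 were tab-separated, unlike the others, and their values were whole numbers in every case. Gene coordinates came from the GENCODE vM21 annotation of the same build.

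The files held 62838 cells. Cells with fewer than 300 genes or with 20% or more mitochondrial counts were left out, which kept 59413 cells. Doublets were scored per well with Scrublet in scanpy 1.11.5 (expected rate 0.06), and 1376 cells with a score above 0.25 (2.32%) were left out, leaving 58037. Before doublets were dropped, counts were scaled to the cell total and log-transformed, 2000 variable genes (no mitochondrial, ribosomal, haemoglobin or sex-linked genes) and 30 principal components were taken, and a graph of 20 neighbours was clustered with Leiden at resolution 1 (igraph 0.11.9), which gave 37 clusters. Clusters were named from marker genes as resembling a cell type, and a cluster whose leading genes went against its name stayed unnamed. The names are therefore rebuilt and need not match those used by the authors. A class was tested only with at least 20 cells in each of the 6 samples, which left out cardiomyocyte-, chondrocyte-, epithelial-, neutrophil-, plasma cell- and skeletal muscle-like cells. The endothelial class was made of clusters 22 and 28.

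Raw counts were summed per sample and class, since cells are not replicates. Sums were compared between diets with the edgeR 4.0.16 quasi-likelihood test (robust fit, TMM factors, default filter on low counts) and Benjamini-Hochberg adjustment at 0.05. Gene lists, 35 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were measured, adjusted over the lists of a class, with an estimated correlation and fry as alternatives. The list tests, the markers, the tests and the rule for named genes were fixed before the data were examined. That rule names Klf2 and Vcam1 in every class, the 10 rising and 10 falling genes with the largest change (5 and 5 outside the main classes) among called genes with a mean of at least 20 CPM and no overlap between groups, and up to 4 members with the smallest adjusted p of each list described. Haemoglobin genes, sex-linked genes and unnamed gene models were left out of the ranking. A gene named outside this rule is said to have been chosen after its values were seen.

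Endothelial cells were thinned at random (fixed seed) to 1000 UMIs and called Vcam1-positive with at least 1 Vcam1 UMI. The 12 sums of positive and negative cells of the 6 samples were compared with the sample as a block, Vcam1 itself left out, and the diet effect was compared between them through an interaction term. Shares of cells were compared by exact two-sided permutation of 3 against 3 samples, whose smallest p is 0.1. Single-sample shares carry 95% Wilson intervals, and a share of 0 carries the limit that 3 counts would give.

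The gene test was tested on simulated data made from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 76% and 99% of them in endothelial cells (15 false calls), 53% and 96% in smooth muscle cells (11 false calls), 74% and 98% in fibroblasts (12 false calls) and 62% and 95% in macrophages (10 false calls). The changed genes were drawn from those with a mean of at least 20 CPM, so these rates do not cover rarer genes. Each gene was simulated on its own, without the structure that the real samples share.

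Alternatives were DESeq2 1.42.0, median-of-ratios size factors in edgeR, no filter on low counts, the replicate number as a block, each sample left out in turn, doublets kept, a mitochondrial limit of 10%, a minimum of 1000 genes, thinning to 1000 or 2000 UMIs or none, at least 2 Vcam1 UMIs, and blood cell classes left out of the denominator of the shares. Single wells, single endothelial clusters, the filters on cells for the share of Vcam1-positive cells, both samples numbered 3 left out and controls 2 and 3 left out were added after the data had been seen. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.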

Results

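Single-cell RNA was sequenced from mouse aorta by droplet capture, with each captured transcript counted once by its unique molecular identifier (UMI). The mice were C57B/6J animals aged 18 weeks on a normal (control) or a high-fat diet, with 3 samples per group and 6 in all. Control 1, 2 and 3 held 6623, 18138 and 8620 cells, and high-fat diet 1, 2 and 3 held 10888, 8268 and 10301 cells. Total counts were 44601353, 83886418 and 41388034 UMIs in the controls and 53170232, 49623463 and 47249838 UMIs in the high-fat diet samples. Median UMIs per cell were 5955, 3969 and 3960 in the controls and 4063, 4844 and 3856 in the high-fat diet samples. After filtering, 58037 cells in 37 clusters remained. The labels do not say that each sample is a separate animal, so the p-values measure only the spread between these samples. Confidence intervals on shares of cells cover counting error only.

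The first question was which cell classes the aortic preparations held and whether their shares differed with diet. Fibroblast-like cells made up 29.5% ± 12.4 (SD, n = 3) of control cells and 38.3% ± 3.60 (SD, n = 3) of high-fat diet cells. Smooth muscle-like cells made up 19.3% ± 9.33 and 24.4% ± 3.89 (SD, n = 3 each), macrophage-like cells 10.8% ± 2.03 and 9.65% ± 4.05, and endothelial-like cells 4.04% ± 2.09 and 6.16% ± 1.69. The endothelial difference of 2.12 percentage points ran from 1.15 without control 2 to 3.23 without control 3. Erythroid-like cells, which carry haemoglobin transcripts, made up 0.545% ± 0.116 of control cells and 2.76% ± 1.40 of high-fat diet cells, with every high-fat diet sample above every control. Among cells with at least 1000 genes the erythroid shares were 0.0371% ± 0.0374 and 0.197% ± 0.110, still without overlap. Mesothelial-like cells, which line serous surfaces, made up 1.24% ± 0.373 and 1.81% ± 0.244, again without overlap. With blood cell classes out of the denominator the mesothelial shares were 1.68% ± 0.762 and 1.96% ± 0.244 and overlapped (exact permutation p = 0.8). Single wells overlapped in both classes. Erythroid shares of 0.804% in well 1 of high-fat diet 1 and 0.933% in well 2 of high-fat diet 2 lay under 1.09% in well 2 of control 2. Mesothelial shares were 3.31% and 0.28% in wells 1 and 2 of high-fat diet 2. B cell-like cells spread most among the controls, with 32, 2470 and 2265 cells in control 1, 2 and 3, and their mean share was 14.6% ± 13.7 in controls and 2.18% ± 1.84 on the high-fat diet. By exact two-sided permutation of 3 against 3 samples, the erythroid and mesothelial differences each had p = 0.1, the smallest this design allows, and no class went below 0.6 after Benjamini-Hochberg adjustment. In an edgeR quasi-likelihood test of cells per class the erythroid difference was 2.34 on the log2 scale with an adjusted p of 0.0662, and no class passed. The erythroid class was the only one with an unadjusted p under 0.05 (0.00368). Some clusters came almost wholly from one sample: control 1 gave 1125 of the 1132 cells of a smooth muscle cluster, 450 of the 455 cells of a macrophage cluster and 1622 of the 1660 cells of a fibroblast cluster. High-fat diet 1 and 2 together gave 654 and 1873 of the 2551 cells of another smooth muscle cluster. Well 1 of control 1 held 1220 smooth muscle-like, 460 macrophage-like and 1673 fibroblast-like cells, and well 2 held 683, 192 and 799. Smooth muscle-like cells numbered 683 and 1978 in well 1 of high-fat diet 1 and 2, and 1759 and 242 in well 2. These numbers lie near those of the clusters, which may thus follow single wells. Cells were not counted by cluster and well together.

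**Figure D1:**
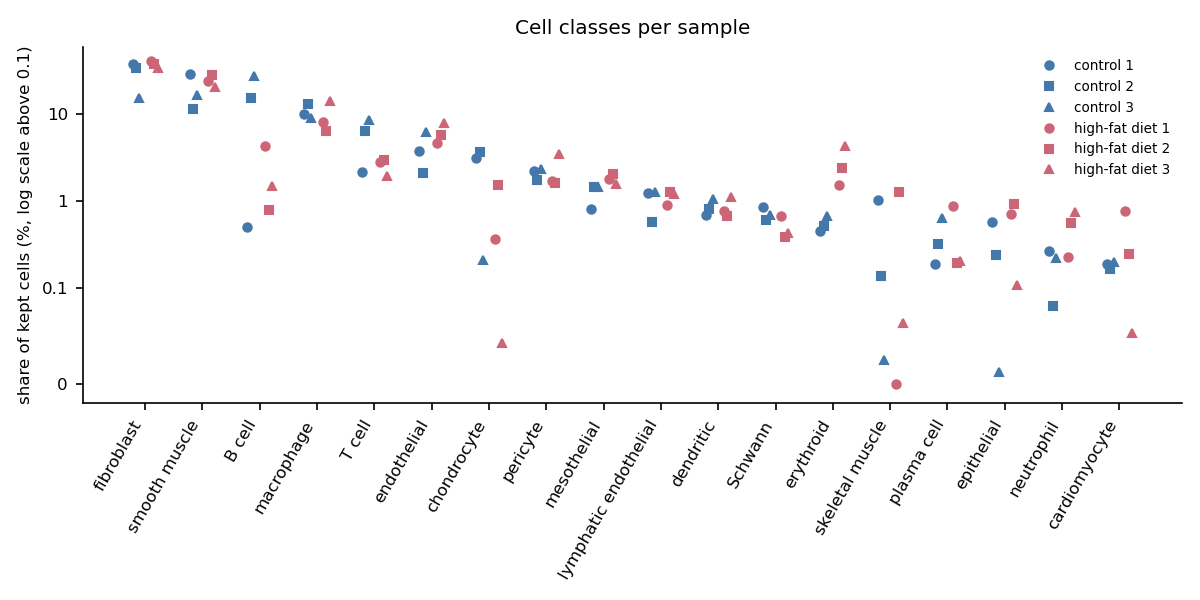
Share of kept cells in each named cell class (vertical axis, percent, log scale above 0.1), one point per sample, with controls in blue and high-fat diet samples in red. As shares of all kept cells, erythroid and mesothelial cells lay higher in all 3 high-fat diet samples than in all 3 controls. B cells ranged from 0.498% to 27.8% among the controls, and the mesothelial shares overlapped once blood cell classes were left out of the denominator.

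The central comparison asked which genes differed with diet in endothelial cells. Of these, 2102 lay in the capillary-like cluster 22 and 673 in the arterial-like cluster 28, so the sums weigh mostly capillary-like cells. Cluster 28 held 29.6% of endothelial cells in controls and 21.2% on the high-fat diet, so the mix differed too. Alyref, which couples mRNA to nuclear export, rose by 1.91 (SE 0.21) on the log2 scale, from 29.3 ± 8.90 to 113 ± 14.6 CPM (counts scaled to the class sum, SD, n = 3 each, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0150). That sum counts only genes that passed the filter, with TMM factors, so CPM of different tests are not on one scale. P4ha1, a subunit of the collagen prolyl hydroxylase, rose by 1.66 (SE 0.17), from 28.5 ± 5.59 to 89.4 ± 8.91 CPM (edgeR adjusted p = 0.0150). Hspb1, a small heat shock protein, rose by 1.08 (SE 0.14), from 764 ± 82.0 to 1609 ± 119 CPM (edgeR adjusted p = 0.0398). Cirbp, a cold-inducible RNA-binding protein, fell by 1.38 (SE 0.17), from 125 ± 19.4 to 48.0 ± 7.99 CPM (edgeR adjusted p = 0.0375). These were the 4 genes past the threshold among 10585 tested in sums of 241, 340 and 511 control cells and 476, 451 and 756 high-fat diet cells. Each sum held 1283747 to 2964577 UMIs. Without adjustment 1335 genes had p under 0.05, DESeq2 called 58 genes, and 1978 genes (18.7%, where chance gives 10%) had groups that did not overlap. The count was 179 without control 1, 8 without control 3 and 0 without high-fat diet 1 or 2. It was 42 in cluster 22 alone and 2 in cluster 28 alone, each over its own tested genes. Hspb1 lost its call without control 2 (edgeR adjusted p = 0.125), control 3 (0.0751) or high-fat diet 1 (0.193), 2 (0.340) or 3 (0.107). P4ha1 and Alyref lost theirs without high-fat diet 1 (0.148) or 2 (0.194), and Cirbp without control 3 (0.0506) or high-fat diet 1 (0.193) or 2 (0.302).

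In the mm10 (GRCm38) build, Alyref (ENSMUSG00000025134) lies on chromosome 11 from 120592121 to 120598365 and P4ha1 (ENSMUSG00000019916) on chromosome 10 from 59323296 to 59373304. Hspb1 (ENSMUSG00000004951) lies on chromosome 5 from 135887919 to 135889563 and Cirbp (ENSMUSG00000045193) on chromosome 10 from 80165985 to 80172786. The title genes are Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656) and Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688).

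Klf2, a flow-responsive transcription factor of quiescent endothelium, stood at 635 ± 105 CPM in control endothelial cells and 1175 ± 394 CPM on the high-fat diet (SD, n = 3 each). All 3 high-fat diet samples (974, 922 and 1629 CPM) lay above all 3 controls (515, 710 and 681 CPM), a log2 fold change of 0.89 (SE 0.23) that did not pass (edgeR quasi-likelihood, unadjusted p = 0.00442, Benjamini-Hochberg adjusted p = 0.236). DESeq2 gave Klf2 an adjusted p of 0.0276, the lowest of all alternatives, whose adjusted p ranged up to 0.685. Its log2 fold change was 0.93 in the capillary-like cluster 22 alone (edgeR adjusted p = 0.129). In the arterial-like cluster 28 alone it was 0.76 (edgeR adjusted p = 0.685). Klf4, a related factor, had a log2 fold change of 0.69 and S1pr1, a receptor that seals endothelial junctions, 0.38 (-0.10 in well 1 alone), with edgeR adjusted p of 0.352 and 0.339. In the list of the Klf2 program and shear response 0 of 13 measured members passed and 10 had positive fold changes. Camera gave the list an adjusted p of 0.0667 (adjusted p = 0.599 with an estimated correlation), with 0 calls adjusted over the list alone. It passed without control 2 (camera adjusted p = 0.0045) or high-fat diet 2 (0.026). Vcam1, an adhesion receptor for leukocytes, stood at 173 ± 109 CPM in controls and 215 ± 20.6 CPM on the high-fat diet, a log2 fold change of 0.31 (SE 0.48, edgeR adjusted p = 0.843) that turned to -0.046 without control 3 and -0.035 after thinning. Icam1, another leukocyte adhesion receptor, had a log2 fold change of 0.50 (edgeR adjusted p = 0.369). Of the 15 measured leukocyte adhesion and chemokine genes 0 passed and 12 had positive fold changes. Camera gave this list an adjusted p of 0.0790 (adjusted p = 0.572 with an estimated correlation), with 0 calls adjusted over the list alone, and it passed without control 2 (0.015) or high-fat diet 1 (0.0379).

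**Figure D2:**
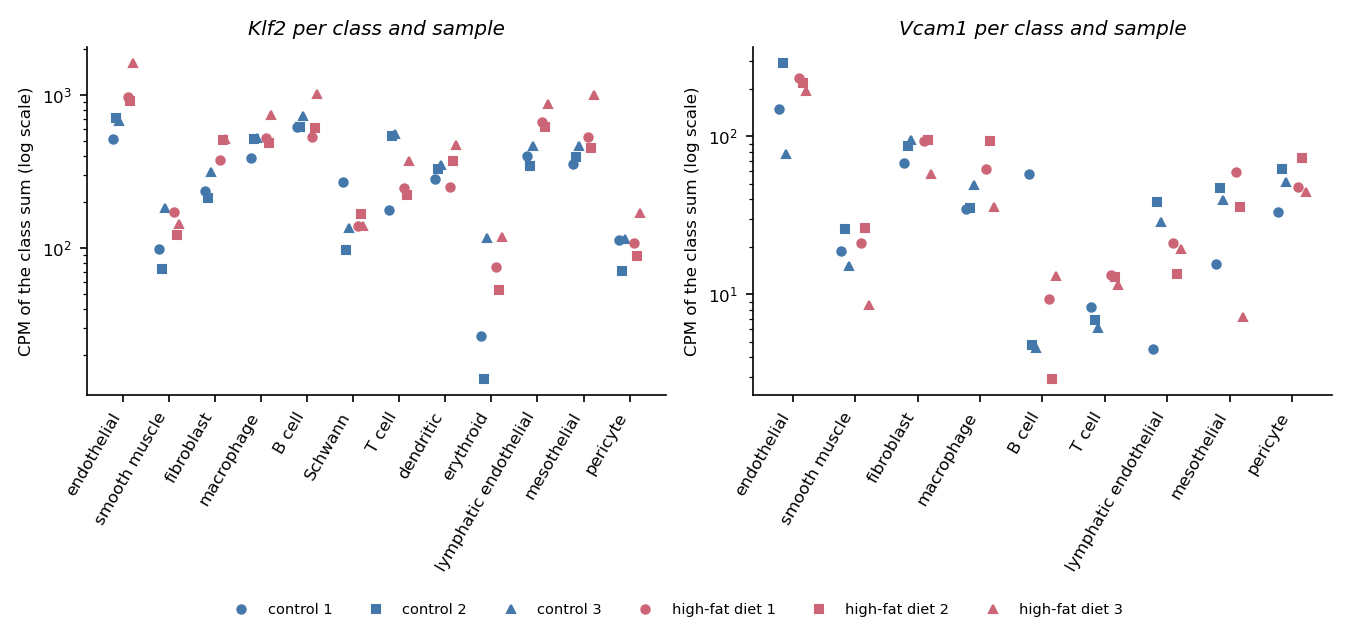
Klf2 (left) and Vcam1 (right) in CPM of the summed cells of each class (vertical axis, log scale), one point per sample, with controls in blue and high-fat diet samples in red. Endothelial Klf2 lay between 922 and 1629 CPM in the high-fat diet samples and between 515 and 710 CPM in the controls, while endothelial Vcam1 overlapped between the diets.

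Heat shock genes formed the list with the smallest camera p in endothelial cells. In the heat shock list 1 of 14 measured members rose (Hspb1), 13 did not pass, and the median log2 fold change was 0.89 (camera adjusted p = 1.76e-14, adjusted p = 0.358 with an estimated correlation). Adjusted over the list alone, 8 heat shock genes rose and 1 fell. Hsp90ab1 and Hspa8, cytosolic chaperones, had log2 fold changes of 0.88 and 0.93 (edgeR adjusted p = 0.0555 each, 0.0122 each without control 1). Of the 17 measured members of the unfolded protein response 0 passed and 13 had positive fold changes, with a median of 0.60. The set passed (camera adjusted p = 6.11e-11, adjusted p = 0.358 with an estimated correlation), and 9 members rose adjusted over the list alone. Hspa5, Hsp90b1 and Calr, chaperones of the endoplasmic reticulum, had log2 fold changes of 1.35, 0.96 and 0.82 (edgeR adjusted p = 0.0672, 0.0555 and 0.0555, without control 1 0.0346, 0.0197 and 0.0271). Antigen presentation genes went the other way: all 7 measured MHC class II genes, among them Cd74, the invariant chain (-0.47, edgeR adjusted p = 0.319, 0.25 in well 1 alone), had negative fold changes. Their median was -0.49 (camera adjusted p = 2.22e-04, adjusted p = 0.448 with an estimated correlation, 0 calls adjusted over the list alone). B cell-like cells, with the class II gene H2-DMb2 among their leading genes, made up 14.6% ± 13.7 of control cells and 2.18% ± 1.84 of high-fat diet cells. Whether their RNA lay in these endothelial sums was not tested. Of 14 MHC class I presentation genes 12 had negative fold changes and 0 passed. Their median was -0.21 (camera adjusted p = 0.0168, adjusted p = 0.611 with an estimated correlation, 0 calls adjusted over the list alone). The class I call was lost without control 2 (camera adjusted p = 0.17), control 3 (0.064), high-fat diet 1 (0.073) or high-fat diet 3 (0.065). Small negative fold changes ran through 35 of 36 nuclear genes of oxidative phosphorylation (median -0.24, camera adjusted p = 3.83e-06) and all 31 cytosolic ribosome genes (median -0.33, camera adjusted p = 4.51e-09). No member of either list passed, over all genes or adjusted over the list alone, and each list had adjusted p = 0.611 with an estimated correlation. Genes of other cell types and of mitochondria moved in the same sums, with 0 members passing over all genes. Smooth muscle contraction genes were positive in 16 of 17 members (median 0.47, camera adjusted p = 0.00565, adjusted p = 0.700 with an estimated correlation), a call lost without control 3 (0.111) or high-fat diet 2 (0.263). Mitochondrially encoded genes were positive in 12 of 13 (median 0.34, camera adjusted p = 0.00178, adjusted p = 0.611 with an estimated correlation), a call lost without control 1 (0.185) or high-fat diet 3 (0.206). All 7 adipocyte genes were negative (median -2.46, camera adjusted p = 0.00430, adjusted p = 0.609 with an estimated correlation), the largest median of the called lists. One of them, Cfd, stood at 60.2, 62.5 and 405 CPM in control 1, 2 and 3 and 18.4, 29.3 and 22.2 CPM in high-fat diet 1, 2 and 3. Over the 4 main classes camera called 51 of 135 list tests, 0 of them with an estimated correlation, and fry called 1. In 13 tests, none of them called, the median, the mean and the test differed in sign.

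**Figure D3:**
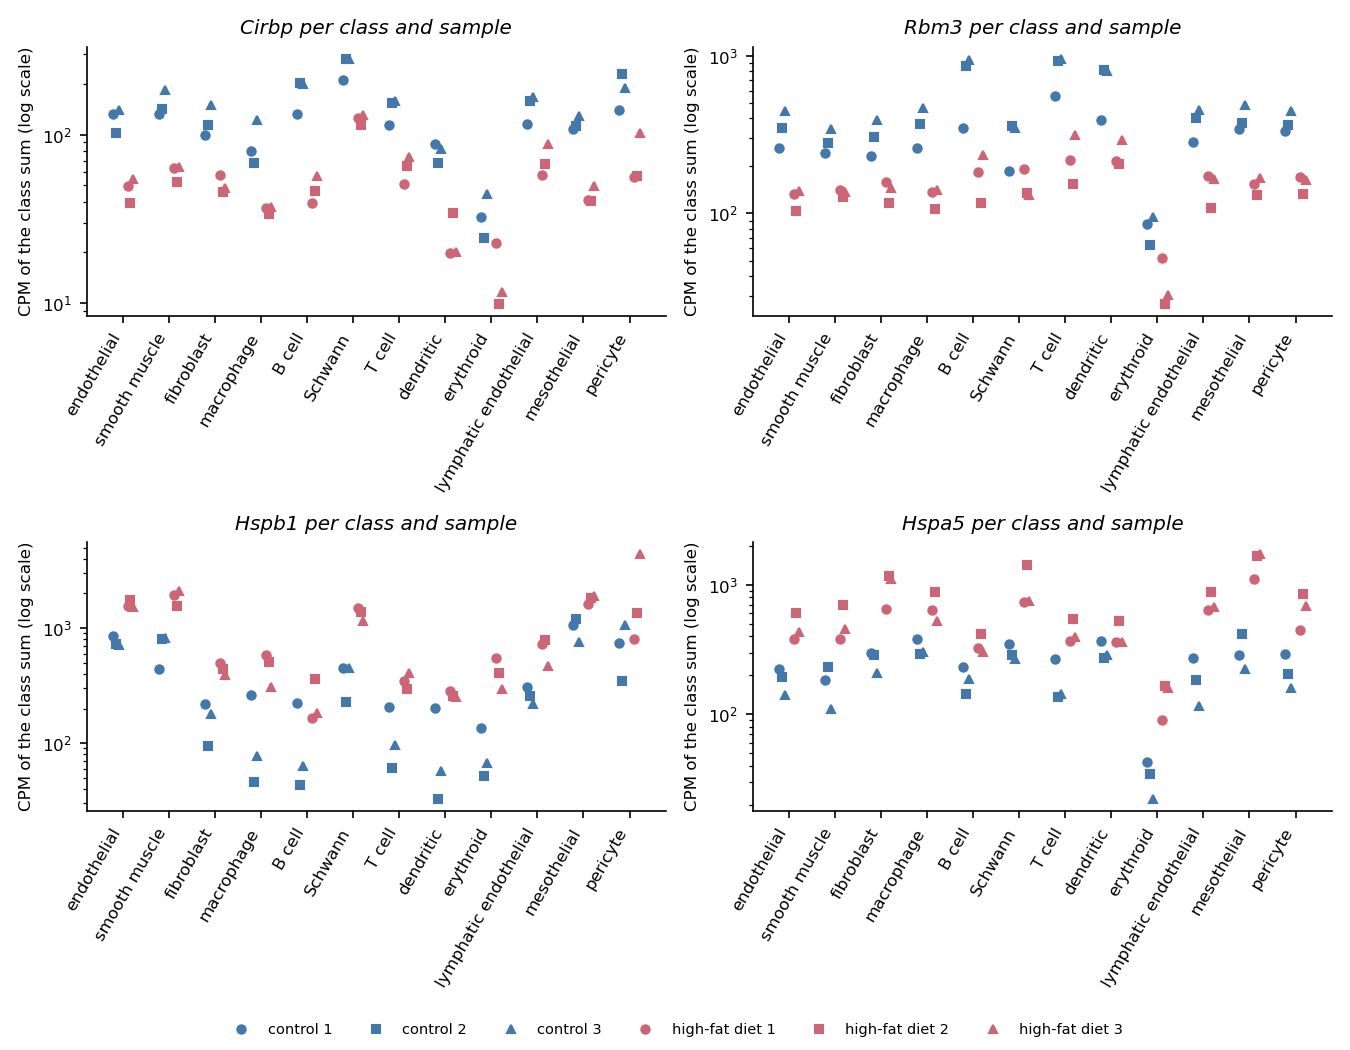
Cirbp, Rbm3, Hspb1 and Hspa5 in CPM of the summed cells of each class (vertical axes, log scale), one point per sample, with controls in blue and high-fat diet samples in red. Cirbp was lower in every high-fat diet sample than in every control in 12 of 12 classes, and Hspa5 higher in 11 of 12.

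For smooth muscle cells, the contractile layer of the vessel wall, the question was the same. Heat shock genes had positive fold changes in 14 of 14 measured members with a median of 0.91 on the log2 scale. They were led by Hsph1, a chaperone cofactor, at 1.88 (SE 0.22, 35.3 ± 8.47 CPM in controls and 130 ± 21.8 CPM on the high-fat diet, SD, n = 3 each, edgeR quasi-likelihood adjusted p = 0.109). The list passed as a set (camera adjusted p = 9.58e-25, adjusted p = 0.170 with an estimated correlation), and 10 members rose adjusted over the list alone while 0 of 14 passed over all genes. In the unfolded protein response 16 of 19 members had positive fold changes (median 0.66, camera adjusted p = 2.13e-16, adjusted p = 0.170 with an estimated correlation). Of these 9 rose adjusted over the list alone and 0 over all genes, with Sdf2l1 at 1.55 and Manf, a secreted stress-induced factor, at 1.28 (edgeR adjusted p = 0.109 each). Lipid uptake and fatty acid handling genes had positive fold changes in 16 of 20 members (median 0.32, camera adjusted p = 6.51e-04, adjusted p = 0.170 with an estimated correlation), with 0 calls adjusted over the list alone or over all genes. Among them were the lipid carrier Fabp4 at 0.88 and the lipid droplet coat gene Plin2 at 0.57 (edgeR adjusted p = 0.495 and 0.501). This was the list that fry called (adjusted p = 0.00539). Capillary endothelial genes, Fabp4 among them, were positive in the same sums in 14 of 15 members (median 0.49, camera adjusted p = 4.90e-05, adjusted p = 0.468 with an estimated correlation). Adipocyte genes were negative in 6 of 7 (median -1.10, camera adjusted p = 0.00175, adjusted p = 0.468 with an estimated correlation), a call lost without high-fat diet 1 (0.0937). Mitochondrially encoded genes were positive in 10 of 13 (median 0.12, camera adjusted p = 0.0489, adjusted p = 0.771 with an estimated correlation), a call lost without control 1 (0.200) or 2 (0.0561) or high-fat diet 3 (0.579). All 8 MHC class II genes had negative fold changes (median -0.86, camera adjusted p = 1.54e-06, adjusted p = 0.420 with an estimated correlation). So had 20 of 22 fibrillar collagen and matrix genes (median -0.36, camera adjusted p = 3.29e-04, adjusted p = 0.468 with an estimated correlation), with 0 calls over all genes or adjusted over either list alone. For the class II genes, B cell-like cells made up 14.6% ± 13.7 of control cells and 2.18% ± 1.84 of high-fat diet cells. Whether B cell RNA lay in the smooth muscle sums was not tested. Col3a1, a fibrillar collagen, stood at -0.55 (edgeR adjusted p = 0.417), and the collagen call was lost without control 2 (camera adjusted p = 0.053). Cebpb, a transcription factor of inflammation and fat cell formation, had a log2 fold change of 2.94 (SE 0.32, edgeR adjusted p = 0.109) and passed without control 3 (0.0318). Klf2 stood at 0.31 (edgeR adjusted p = 0.782). Of 13339 genes edgeR called 0, 1207 had an unadjusted p under 0.05 and DESeq2 called 91. For 2086 genes (15.6%, where chance gives 10%) the diets did not overlap, and without control 3 edgeR called 4. Of the smooth muscle cells, 1 cluster came from control 1 and 1 from high-fat diet 1 and 2, as given above.

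In fibroblasts, the matrix-producing cells of the outer wall, the unfolded protein response was the list with the smallest camera p. Of its 19 measured members 18 had positive fold changes with a median of 0.90 (camera adjusted p = 4.18e-29, adjusted p = 0.178 with an estimated correlation), and 12 rose adjusted over the list alone while 0 passed over all genes. Manf had a log2 fold change of 1.73 (SE 0.18), from 166 ± 25.4 to 551 ± 95.1 CPM (SD, n = 3 each), and Creld2, a chaperone-like protein, of 1.81 (SE 0.20), from 31.9 ± 5.13 to 112 ± 23.9 CPM, each with an edgeR quasi-likelihood adjusted p of 0.0665. Hspa5 stood at 1.88 (edgeR adjusted p = 0.122). All 14 heat shock genes had positive fold changes (median 0.69, camera adjusted p = 1.11e-16, adjusted p = 0.178 with an estimated correlation, 8 rose adjusted over the list alone and 0 over all genes). All 14 MHC class I genes had negative fold changes (median -0.37, camera adjusted p = 1.79e-06, 4 fell adjusted over the list alone), among them the immunoproteasome subunit Psmb9 at -0.74 (edgeR adjusted p = 0.312). So had all 8 MHC class II genes (median -0.77, camera adjusted p = 1.97e-05, 0 calls adjusted over the list alone). Each list had adjusted p = 0.576 with an estimated correlation and 0 members past the test over all genes. Here too the class II genes stand beside B cell-like shares of 14.6% ± 13.7 in controls and 2.18% ± 1.84 on the high-fat diet. Whether B cell RNA lay in the fibroblast sums was not tested. Fibrillar collagen and matrix genes were negative in 17 of 22 members (median -0.31, camera adjusted p = 0.00352, adjusted p = 0.861 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Col1a1 stood at -0.92 and Col3a1 at -0.90 (edgeR adjusted p = 0.277 and 0.294). The collagen call was lost without control 2 (camera adjusted p = 0.49) or high-fat diet 2 (0.095). Genes of other cell types moved in these sums too. Adipocyte genes were negative in 7 of 8 (median -1.48, camera adjusted p = 1.97e-05, adjusted p = 0.536 with an estimated correlation). Capillary endothelial genes were positive in 13 of 15 (median 0.37, camera adjusted p = 0.0319, adjusted p = 0.861 with an estimated correlation), a call lost without control 2 (0.821) or high-fat diet 3 (0.293). Cebpb stood at 2.52 (edgeR adjusted p = 0.279, 0.0321 without control 3), and Klf2 at 0.88 (SE 0.20, edgeR adjusted p = 0.252) with no overlap between the diets. Of 13793 genes edgeR called 0, 1441 had an unadjusted p under 0.05 and DESeq2 called 202. For 2431 genes (17.6%, where chance gives 10%) the diets did not overlap, and without control 3 edgeR called 2. Control 1 filled 1 fibroblast cluster, as given above.

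In macrophages, heat shock genes again had positive fold changes in 14 of 14 measured members (median 0.93, camera adjusted p = 1.78e-16, adjusted p = 0.363 with an estimated correlation, 7 rose adjusted over the list alone and 0 over all genes). Hsp90ab1 stood at 0.93 (SE 0.17, 746 ± 99.6 CPM in controls and 1421 ± 193 CPM on the high-fat diet, SD, n = 3 each, edgeR quasi-likelihood adjusted p = 0.417, and 0.0204 without control 1). Unfolded protein response genes were positive in 13 of 15 members (median 0.57, camera adjusted p = 4.41e-13, adjusted p = 0.363 with an estimated correlation, 9 rose adjusted over the list alone and 0 over all genes). Inflammatory macrophage genes were positive in 10 of 11 members (median 0.50, camera adjusted p = 9.24e-07, adjusted p = 0.363 with an estimated correlation, 3 rose adjusted over the list alone and 0 over all genes). Among them were Cebpb at 2.69 (edgeR adjusted p = 0.212, 0.0263 without control 1), the neutrophil chemokine Cxcl2 at 0.75 and the endotoxin co-receptor Cd14 at 0.50 (edgeR adjusted p = 0.488 each). In well 1 alone Cxcl2 stood at -1.07 and Cd14 at -0.56, and in well 2 alone at 2.26 and 1.31 (edgeR adjusted p = 0.00542 and 0.0297). Plin2 had a log2 fold change of 1.24 (SE 0.26), from 152 ± 48.5 to 360 ± 66.6 CPM (edgeR adjusted p = 0.417, 0.0217 without control 1). Its lipid uptake list was positive in 15 of 19 members (median 0.25, camera adjusted p = 0.00829, 0.12 without control 1, adjusted p = 0.363 with an estimated correlation, 1 rose and 1 fell adjusted over the list alone, 0 over all genes). Resident macrophage genes were negative in 10 of 13 members (median -0.22, camera adjusted p = 0.0482, adjusted p = 0.721 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Timd4, an apoptotic cell receptor, stood at -0.53 (edgeR adjusted p = 0.488). The call of the resident list was lost without control 2 (camera adjusted p = 0.43), control 3 (0.14) or high-fat diet 2 (0.53). MHC class I genes were negative in 13 of 14 members (median -0.36, camera adjusted p = 4.37e-05) and oxidative phosphorylation genes in 35 of 36 (median -0.28, camera adjusted p = 2.35e-07). Each had adjusted p = 0.584 with an estimated correlation and 0 calls over all genes or adjusted over either list alone. Genes of other cell types and of mitochondria moved in these sums. Capillary endothelial genes were positive in 11 of 13 (median 0.65, camera adjusted p = 0.00108, adjusted p = 0.584 with an estimated correlation), a call lost without control 2 (0.0732). Smooth muscle contraction genes were positive in 16 of 18 (median 0.30, camera adjusted p = 0.0192, adjusted p = 0.855 with an estimated correlation), a call lost without control 2 (0.861) or 3 (0.133) or high-fat diet 2 (0.490). Against control 1 alone that list went the other way (camera adjusted p = 2.27e-04). Mitochondrially encoded genes were positive in 12 of 13 (median 0.28, camera adjusted p = 0.00277, adjusted p = 0.636 with an estimated correlation), a call lost without control 1 (0.118) or 3 (0.104) or high-fat diet 3 (0.206). Klf2 stood at 0.29 (edgeR adjusted p = 0.706). Of 10720 genes edgeR called 0, 885 had an unadjusted p under 0.05 and DESeq2 called 30. For 1528 genes (14.3%, where chance gives 10%) the diets did not overlap, and without control 1 edgeR called 437. Control 1 filled 1 macrophage cluster. Its macrophage sum held 2034 CPM of Acta2, a smooth muscle gene, against 239 and 474 CPM in control 2 and 3 and 1774, 2468 and 1013 CPM in high-fat diet 1, 2 and 3.

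The 8 other classes with enough cells gave 81 calls in all, more in lymphatic endothelial cells than in any other class (38 of 7484 genes, 30 higher and 8 lower on the high-fat diet). There Klf2 rose by 0.84 (SE 0.17) on the log2 scale, from 405 ± 61.4 to 725 ± 133 CPM (SD, n = 3 each, edgeR quasi-likelihood adjusted p = 0.0172), a call lost without control 2 (0.136), high-fat diet 1 (0.0942) or high-fat diet 3 (0.149). P4ha1 rose by 1.73 in the same cells (edgeR adjusted p = 0.00119) and passed whichever sample was left out (highest edgeR adjusted p 0.0174). Rbm3, a cold-inducible RNA-binding protein like Cirbp, fell by 1.36 (edgeR adjusted p = 0.00679, 0.0666 without control 2) and Cd74 fell by 1.06 (edgeR adjusted p = 0.0124, lost without high-fat diet 1, 0.132, or 2, 0.0811). Cebpb rose by 2.89 in mesothelial cells and by 2.87 in pericytes (edgeR adjusted p = 0.0013 and 0.00802), and passed in each whichever sample was left out (highest edgeR adjusted p 0.0171 and 0.0366). In T cells Cebpb rose by 2.57 (edgeR adjusted p = 0.00463, lost without high-fat diet 1, 0.0673, or 2, 0.0578). Alyref rose by 2.11 and Sdf2l1 by 1.89 in pericytes (edgeR adjusted p = 0.00802 each, 0.0554 each without high-fat diet 2). In Schwann cells Alyref rose by 3.50 and Hspb1 by 1.86 (edgeR adjusted p = 0.0158 each, 0.102 each without high-fat diet 1). Klf2 in T cells had a log2 fold change of -0.61 (edgeR adjusted p = 0.584) and passed only without control 1 (0.00695). Across the 12 classes Klf2 had positive fold changes in 10 and was called in 1, and Vcam1, measured in 9, had positive fold changes in 5 and was called in 0. Among genes singled out after their values were seen, Cirbp was lower in every high-fat diet sample than in every control in 12 of 12 classes (called in 6, log2 fold changes from -2.0 to -1.04). Alyref was higher in 11 of 11 (called in 3) and Cebpb higher in 10 of 10 (called in 6). The other calls were 7 in B cells, 7 in Schwann cells, 14 in T cells, 2 in dendritic cells, 7 in mesothelial cells and 6 in pericytes. There were 0 in erythroid cells, where 140 genes had an unadjusted p under 0.05 and DESeq2 called 6. The total of 81 moved to 2409 without control 1, 46 without control 2, 39 without control 3, and 23, 48 and 51 without high-fat diet 1, 2 and 3.

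The series title concerns endothelial cells that carry Vcam1, so the share of endothelial cells with a Vcam1 UMI was compared between diets after each cell was thinned to 1000 UMIs. That share was 10.2% ± 4.08 in controls and 9.15% ± 2.45 on the high-fat diet (SD, n = 3 each, exact two-sided permutation p = 0.7, smallest possible 0.1). In control 1, 2 and 3 it was 24 of 241 cells (9.96%, 95% Wilson interval 6.78 to 14.4), 49 of 340 (14.4%, 11.1 to 18.5) and 32 of 511 (6.26%, 4.47 to 8.71). In high-fat diet 1, 2 and 3 it was 57 of 476 cells (11.97%, 9.36 to 15.2), 34 of 451 (7.54%, 5.45 to 10.4) and 60 of 756 (7.94%, 6.22 to 10.1). B cells, which should lack the gene, had a share of 0.380% ± 0.329 in controls and 0.544% ± 0.484 on the high-fat diet, with 0 of 32 in control 1, which allows up to 9.38%. T cells had 0.354% ± 0.309 and 1.09% ± 0.657. Median depths before thinning were 2957 to 4080 UMIs in endothelial cells, 2208 to 4974 in B cells and 2942 to 4338 in T cells. Fibroblasts (7.47% ± 1.24 and 6.78% ± 1.27), macrophages (2.99% ± 0.868 and 4.71% ± 1.27) and pericytes (3.53% ± 1.24 and 5.66% ± 2.60) also lay above the B and T cell level. Without thinning the endothelial share was 24.01% ± 8.17 in controls and 21.02% ± 2.65 on the high-fat diet (exact permutation p = 0.6). The difference of -1.06 percentage points turned to 1.04 without control 2 and stood at -3.04 without control 3 and -2.47 without high-fat diet 1, -0.257 without high-fat diet 2 and -0.456 without high-fat diet 3. Among cells with at least 1000 genes, a filter added after the data were seen, it was 0.42 (9.97% ± 4.62 and 10.39% ± 0.782, exact permutation p = 0.9). Endothelial cells formed a capillary-like cluster led by Gpihbp1 and Fabp4 (2102 cells, cluster 22) and an arterial-like cluster (673 cells, cluster 28). The leading genes of cluster 28 held Gkn3, Bmx and Gja5 of the arterial list, but also Vwf of the venous list, so its name is approximate. In a separate random thinning per cluster, the share was 28.9% ± 11.3 in controls and 37.4% ± 3.75 on the high-fat diet in cluster 28 (exact permutation p = 0.4), and 1.68% ± 0.60 and 2.01% ± 0.613 in cluster 22 (exact permutation p = 0.6).

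**Figure D4:**
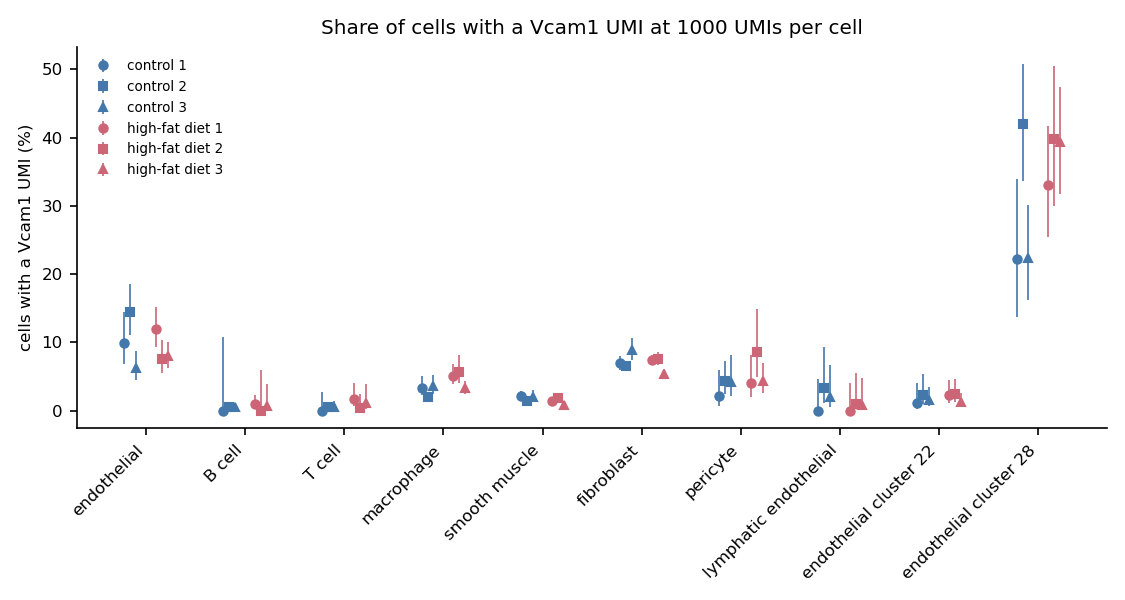
Percent of cells with at least 1 Vcam1 UMI after thinning to 1000 UMIs per cell (vertical axis) for each class, one point per sample with its 95% Wilson interval, controls in blue and high-fat diet samples in red. Endothelial shares ran from 6.26% to 14.4% with the diets overlapping, and B and T cells gave the background.

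To describe that population, Vcam1-positive and Vcam1-negative endothelial cells of the same samples were compared at 1000 UMIs per cell. Positive cells had higher levels of arterial genes and lower levels of the capillary lipid-handling set. Cytl1, a small secreted protein, was higher by 2.57 (SE 0.20) on the log2 scale, at 6873 ± 3039 CPM in positive and 1146 ± 503 CPM in negative cells (SD, n = 6 samples each, edgeR quasi-likelihood adjusted p = 3.19e-09, higher in 6 of 6 samples). Gja5, an arterial gap junction protein, was higher by 2.66 (SE 0.32, edgeR adjusted p = 1.14e-14, 6 of 6). Fabp4 was lower, with a log2 fold change of -2.65 (SE 0.12, edgeR adjusted p = 6.42e-60, lower in 6 of 6), and so was Gpihbp1, the capillary anchor of lipoprotein lipase, at -2.69 (SE 0.17, edgeR adjusted p = 4.60e-50, 6 of 6). Of 3399 genes 543 passed, 261 higher and 282 lower in positive cells, and 893 had an unadjusted p under 0.05. All 15 capillary and lipid-handling genes were lower (median -2.49), all 15 of them also when adjusted over the list alone. Of 14 arterial genes 10 were higher, 0 lower and 4 did not pass (median 1.32, 12 calls adjusted over the list alone), among them Clu (2.10, 5 of 6 samples), a secreted chaperone. Of 14 lipid uptake genes 11 were lower, 0 higher and 3 did not pass (median -2.46, 12 calls adjusted over the list alone), among them the fatty acid receptor Cd36 (-2.41) and the transcription factor Tcf15 (-2.49). Adhesion and chemokine genes were higher in 5, lower in 2 and not past the test in 2 of 9 (median 1.02, 7 calls adjusted over the list alone), with Selp at 2.34, Icam1 at 1.41 and the chemokine Cxcl12 at -2.46. The Klf2 program split, with 6 of 13 higher, 2 lower and 5 not past the test (median 0.12, 8 calls adjusted over the list alone). Its most significant member, the water channel Aqp1, was lower, at -1.35 (edgeR adjusted p = 2.39e-18), while Cyp1b1 stood at 2.20 (edgeR adjusted p = 1.22e-08) and the receptor Tek at 0.95 (edgeR adjusted p = 1.75e-04). Genes of other cell types and of RNA quality moved as well. Venous endothelial genes were higher in 3 of 7 and lower in 0 (Vwf at 1.61, Il6st at 0.92), and fibrillar collagen and matrix genes higher in 8 of 19 and lower in 1 (Eln at 1.52). Erythroid genes were lower in 4 of 5 and higher in 1, with Hba-a2, a haemoglobin chain, at -3.53 (edgeR adjusted p = 6.25e-58). Immediate early genes were lower in 5 of 12 (Btg2 at -1.20) and mitochondrially encoded genes in 4 of 12, with 0 higher in either. Klf2 itself stood at 1132 ± 624 CPM in positive and 1155 ± 545 CPM in negative cells, a log2 fold change of -0.04 (SE 0.15, edgeR adjusted p = 0.922, higher in 3 of 6). Kcna5 and Pparg, the regulator of fat storage, each gave 1 UMI in the 256000 UMIs of positive cells against 306 and 227 UMIs in the 2519000 of negative cells. The ratios were 0.0322 (exact 95% interval 8.12e-04 to 0.181) and 0.0433 (0.00109 to 0.244). These intervals pool the UMIs of all 6 samples and cover counting error only, not the spread between samples. Within cluster 28 alone, with fewer cells and genes, edgeR called 8 of 1166 genes (110 with an unadjusted p under 0.05). These were Ly6c1 at 0.90, Ly6a at 0.73, Dcn at 0.72, Clu at 0.53, Apoe at 0.42, Tm4sf1 at 0.41, Cytl1 at 0.38 and Fabp4 at -0.57. Sorting cells by 1 UMI at this depth is noisy, so each class holds some cells of the other kind.

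**Figure D5:**
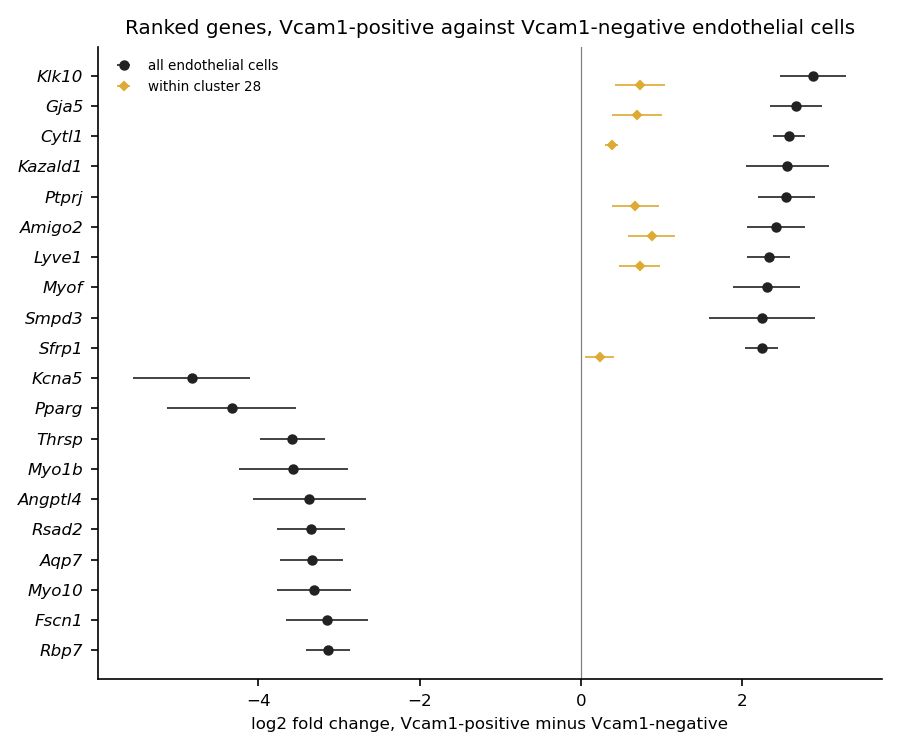
Log2 fold change between Vcam1-positive and Vcam1-negative endothelial cells (horizontal axis, with SE bars) of the 10 ranked genes higher and the 10 lower in positive cells, over all endothelial cells (black) and within cluster 28 where tested (yellow). Cytl1 was 2.57 higher over all endothelial cells and 0.38 higher within cluster 28.

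The last comparison asked how diet acted within Vcam1-positive endothelial cells and whether it acted differently there. Hspb1 rose by 1.44 (SE 0.33) on the log2 scale, from 607 ± 203 to 1711 ± 313 CPM (SD, n = 3 each, edgeR quasi-likelihood adjusted p = 0.0403). Rbm3 fell by 2.35 (SE 0.50), from 779 ± 317 to 143 ± 27.8 CPM (edgeR adjusted p = 0.0317). These were 2 of 613 genes in sums of 24000 to 60000 UMIs, where 39 had an unadjusted p under 0.05 and DESeq2 called 0. The count was also 0 with doublets kept, with a mitochondrial limit of 10% and with at least 1000 genes per cell. Klf2 stood at 996 ± 102 CPM in controls and 2264 ± 841 CPM on the high-fat diet, a log2 fold change of 1.19 (SE 0.32, edgeR adjusted p = 0.0934). CPM in this test was scaled to the 613 genes tested, so it cannot be set against CPM of the other comparisons. In the comparison with negative cells, over 3399 genes, Klf2 stood at 1132 ± 624 CPM in the positive cells. The diet effect on Klf2 in positive cells differed from that in negative cells by 0.22 (SE 0.31, edgeR adjusted p = 0.998). Cytl1 (ENSMUSG00000062329, chromosome 5, 37735519 to 37739820) was the 1 gene of 3399 whose diet effect differed between the classes, by 1.18 (SE 0.25, edgeR adjusted p = 0.00481), where 153 genes had an unadjusted p under 0.05. Left-out samples moved these calls: the count of 2 became 5 without control 1, 6 without high-fat diet 3 and 0 without any other sample. Rbm3 was lost without control 2 (edgeR adjusted p = 0.0940), control 3 (0.0892) or high-fat diet 1 (0.0939) or 2 (0.210). Hspb1 was lost without control 1 (0.0698), 2 (0.0940) or 3 (0.200) or high-fat diet 1 (0.0939) or 2 (0.372). The Cytl1 call was lost without high-fat diet 2 (0.418) or 3 (0.126), and without control 1 a further gene joined Cytl1, for 2 calls.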

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

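Of the tests in this part, that of free Cytl1 RNA and the splits of the samples were chosen after the result was seen. Cytl1 was the 1 gene whose diet effect differed between Vcam1-positive and Vcam1-negative endothelial cells, by 1.18 (SE 0.25) on the log2 scale by the edgeR interaction test (adjusted p = 0.00481; alternatives gave 0.00529 to 1.00, the high end without thinning). The ratio of positive to negative cells was 2.30, 2.34 and 1.32 on the log2 scale in control 1, 2 and 3 and 2.89, 3.64 and 3.11 in high-fat diet 1, 2 and 3.

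Free RNA from chondrocyte-like cells, which differ in number between samples, was tested by taking the Cytl1 level of T cells off each sum: the difference between the diets was then 0.963 of what it had been (1.18 after 1.22), which argues against free RNA as the whole source, although the gap between the lowest high-fat diet and the highest control sample shrank from 0.55 to 0.13. A different mix of the capillary-like and arterial-like clusters could account for it: within cluster 28 the lowest high-fat diet ratio lay 0.48 under the highest control ratio (-0.48), and the means differed by 0.16. Of the 10 splits of the 6 samples, the real one included, 4 gave as many genes as the real 1, with 4 genes as the highest of the others, and 10 splits are too few for a share under 0.05. Those 4 came from the split of control 1 and high-fat diet 1 and 2 from the rest. This points to a structure of the samples or of single wells within them. Apart from the mix, diet was compared only within cluster 28, where the means differed by 0.16 against 1.22 over both clusters and the ratios overlapped. A biological effect of diet on these cells stays open, since overlapping ratios in so few samples cannot exclude it.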

How the results depend on the processing

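Among the alternatives here, the filters on cells for the Vcam1-positive share, single wells, single endothelial clusters, both samples numbered 3 left out, controls 2 and 3 left out, and the unthinned diet test in Vcam1-positive cells were chosen after seeing the data. Where a value moved, the cause was not tested. Diet calls in endothelial cells (4) became 58 with DESeq2, 99 with no filter on low counts, 0 to 179 leaving out each sample, 18 after thinning, 16 without both samples numbered 3, 30 without controls 2 and 3, 0 and 7 in well 1 and well 2 alone, and 42 and 2 in cluster 22 and cluster 28 alone. Smooth muscle calls (0) became 91 with DESeq2, 13 with no filter, 0 to 4 leaving out each sample, 8 after thinning, 1 without both samples numbered 3, 18 without controls 2 and 3, and 8 in well 2. Fibroblast calls (0) became 202 with DESeq2, 18 with no filter, 0 to 2 leaving out each sample, 6 after thinning, 1 without both samples numbered 3, and 1 and 2 in well 1 and well 2. Macrophage calls (0) became 30 with DESeq2, 5 with no filter, 0 to 437 leaving out each sample, 2 after thinning, 3 without controls 2 and 3, and 12 in well 2. The 81 calls in the other classes became 181 with DESeq2, 1160 with no filter, 23 to 2409 leaving out each sample, 122 after thinning, 18 without both samples numbered 3 and 333 without controls 2 and 3. With controls 2 and 3 left out, control 1 is alone and is assumed to vary like the high-fat diet samples.

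The count of 543 between Vcam1-positive and Vcam1-negative cells became 296 without the sample block (no replicate block), 324 with DESeq2, 2373 without thinning, 1241 at 2000 UMIs and 8 within cluster 28, each over its own set of tested genes. The 1 gene with a differing diet effect became 0 to 2 leaving out each sample and 0 without thinning. The 2 diet genes in Vcam1-positive cells became 0 with DESeq2, 0 to 6 leaving out each sample, 0 with doublets kept, 0 with a mitochondrial share under 10% and 0 with at least 1000 genes. The 51 list calls became 0 with an estimated correlation and 1 with fry. The share of Vcam1-positive endothelial cells, -1.06 percentage points over both clusters, differed by 0.33 within cluster 22, 8.53 within cluster 28 and 0.42 with at least 1000 genes, so its direction turned. Cluster 28, where most Vcam1-positive cells lay, held 29.6% of endothelial cells in controls and 21.2% on the high-fat diet. The value over both clusters thus also carries this difference in mix. Endothelial Klf2 kept its direction throughout and passed with DESeq2 (0.89, adjusted p = 0.0276, over a range of 0.0276 to 0.685). Its log2 fold change ran from 0.575 without high-fat diet 3 to 1.20 with controls 2 and 3 left out, and was 0.628 without both samples numbered 3.

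These values changed sign: endothelial S1pr1 to -0.10 and Cd74 to 0.25 in well 1, endothelial Vcam1 to -0.035 after thinning and from -0.046 to 0.93 leaving out each sample, macrophage Cxcl2 to -1.07 and Cd14 to -0.56 in well 1, Klf2 between Vcam1-positive and Vcam1-negative cells to 0.10 without the sample block and from -0.14 to 0.030 leaving out each sample, and its interaction to -0.30 without thinning. Without controls 2 and 3 the endothelial MHC class I list turned (camera adjusted p = 0.688), as did the resident macrophage list (0.265) and the smooth muscle contraction list in endothelial cells (0.243) and macrophages (2.27e-04). Each result counted next is a gene or list in a single class or comparison, so the same gene or list can count more than once. Of the 71 gene results called, 728 alternatives kept the call and 370 lost it without a change of direction. Of the 37 gene results named but not called, 584 alternatives left them so and 73 brought a call. Of the 34 list results called, 294 alternatives kept the call and 110 lost it. The exact test of class shares cannot go below 0.1 and was not run with a sample left out, so only the differences in percentage points are compared: endothelial from 2.12 to 1.15 without control 2, 1.19 without high-fat diet 3, 1.17 with blood classes out of the denominator and 3.23 without control 3, erythroid from 2.21 to 0.16 with at least 1000 genes, fibroblast from 8.85 to 1.77 without control 3, smooth muscle from 5.14 to 1.27 without control 2, B cell from -12.4 to -5.58 with at least 1000 genes, and macrophage from -1.15 to 0.42 without high-fat diet 2, a change of sign. Without control 1 the differences grew to 13.3 for fibroblast, 10.3 for smooth muscle and -19.4 for B cell-like cells, and the mesothelial one fell to 0.350. The erythroid difference fell to 1.45 without high-fat diet 3.

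With the replicate block, endothelial calls went from 4 to 0, those in Vcam1-positive cells from 2 to 0 and those in the other classes from 81 to 82. The other 3 main classes stayed at 0, and list calls went from 51 to 54. Correlations of samples with the same number ran from -0.32 to 0.41 over the 4 main classes. Samples numbered 3 stood at 0.41 in smooth muscle cells and 0.23 in fibroblasts, but in no class did every sample correlate best with its own number: control 1 did so with high-fat diet 2 in each (0.47 in smooth muscle cells). The numbers were not taken as a pairing. Alternatives by well gave no value for classes with too few cells in a well, and Vcam1 could not be tested in classes where it was filtered out. Depth limits what the Vcam1-positive sums can show: they hold 24000 to 60000 UMIs, and 613 genes passed the filter there.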

Other observations

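Of the tests in this part, those of depth and of the gene list splits were written before their results were seen, and those of dissociation, time of day, stromal RNA, interferon and all other splits were chosen after the result was seen. The genes in this paragraph were also chosen after their values were seen. Genes of the daily clock differed among the controls and, without a call, between the diets. Dbp, a clock output gene, was higher in controls 2 and 3 than in the other 4 samples in 9 of 9 classes, and Per3 in 7 of 7, while Dbp in control 1 lay at the level of the high-fat diet samples in 9 of 9. Nr1d2 placed control 1 as Dbp did, within or below the high-fat diet range in 9 of 9 classes, Per3 did so in 4 of 7, and Tef in 1 of 10. Between the diets, fold changes were negative for Dbp in 9 of 9 classes, Per3 in 7 of 7, Tef in 10 of 10 and Nr1d2 in 8 of 9. Arntl, another clock gene, had positive fold changes in 9 of 9. The diets did not overlap for Tef in 8 classes, Per3 in 3, Arntl in 2 and Dbp and Nr1d2 in 0, with 0 calls for each gene. Acta1 and Ckm, skeletal muscle genes, were higher in control 1 than in every high-fat diet sample in 11 of 11 classes, and skeletal muscle-like cells were found mostly in control 1 (66 cells) and high-fat diet 2 (99 cells). Scgb1a1, a gene of airway cells, had positive fold changes in 12 of 12 classes, with the diets overlapping in each and 0 calls.

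Endothelial cells also differed in their makeup. The arterial-like cluster 28 held 29.6% ± 5.94 of endothelial cells in controls and 21.2% ± 4.21 on the high-fat diet (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). The lowest control stood at 26.1% and the highest high-fat diet sample at 26.05%, so the groups nearly touched.

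The widest pattern was that of higher chaperone genes with lower Cirbp and Rbm3 on the high-fat diet across classes. For depth per cell, thinning left at least 0.926 of the heat shock median (0.95, 0.84, 0.70 and 0.96 in endothelial, smooth muscle, fibroblast and macrophage cells against 0.89, 0.91, 0.69 and 0.93). Random thinning keeps the expected share of each gene in a cell and only evens the weight of cells. It shows that the deepest cells did not carry the pattern, and it cannot decide on depth in any other way. A response to dissociation could not be settled: the immediate early list had a positive median in 2 of the 4 main classes. Time of day at harvest cannot be told apart from diet here: control 1, the only control with Dbp at the level of the high-fat diet samples, lay above all of them for Cirbp in 12 of 12 classes, but it also lay below controls 2 and 3 for Rbm3 in 11 of 12 and for Cirbp in 8 of 12, and 1 sample excludes nothing. Diet and handling differences between the groups both stay open as explanations that these data may not separate.

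Control 1 and high-fat diet 1 and 2, set against the other samples, gave 224 macrophage genes where diet gave 0. This points to a structure of the samples or of single wells within them. Of the 196 genes higher in control 1 and high-fat diet 1 and 2, 150 (76.5%, against 10.1% of genes tested) were over 4 times more abundant in smooth muscle or fibroblast sums. RNA of those cells in the macrophage sums may therefore account for much of the 224. Of 18 smooth muscle and fibroblast markers all had positive fold changes and 2 passed, Actg2 at 2.37 (edgeR adjusted p = 0.00233) and Mylk at 1.17 (edgeR adjusted p = 0.0436), while Acta2 (edgeR adjusted p = 0.130) stood at 2034, 1774 and 2468 CPM in those samples and 239 to 1013 CPM in the others. An interferon response could not be settled either, with 9 of 24 measured interferon genes higher, and no other biological explanation was tested.

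Other splits of the 6 samples were counted for each diet result, and the 10 splits are too few for a share under 0.05. Each count of splits includes the real one. In endothelial cells 2 of 10 splits gave as many genes (real 4, highest other 17), in smooth muscle cells 10 (real 0, highest other 3), in fibroblasts 10 (real 0, highest other 0) and in macrophages 10 (real 0, highest other 224). Where the real count was 0 every split gives as many, so those counts of 10 were fixed in advance. In the other classes 2 of 10 gave as many (real 81, highest other 134), in Vcam1-positive cells 2 (real 2, highest other 8), and for the gene lists 4 (real 51, highest other 56). For the heat shock list the real split had the largest median of the 10 in each main class (0.89, 0.91, 0.69 and 0.93 in endothelial, smooth muscle, fibroblast and macrophage cells, highest others 0.66, 0.71, 0.47 and 0.64), and so it had for the unfolded protein response (0.60, 0.66, 0.90 and 0.57, highest others 0.35, 0.54, 0.49 and 0.36). Both lists were chosen after they had led the diet comparison in the same sums, and no other split was given its own leading lists. The main classes also share the same 6 samples, so these ranks are not independent support. The endothelial 17, the 134 and the 8 came from the split of control 1 and high-fat diet 1 and 2 from the rest. This again points to a structure of the samples or of single wells within them. For the Vcam1-positive against Vcam1-negative comparison, 1 of 32 swaps, the real one, gave as many genes (real 543, highest other 76), the smallest share that 32 swaps allow. Sorting on Vcam1 also separated the endothelial clusters. The mean positive shares in controls and on the high-fat diet were 28.9% and 37.4% in cluster 28 and 1.68% and 2.01% in cluster 22. The swaps therefore show that the classes differed over the samples, and cannot tell Vcam1 from cluster.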
